A study of Mus musculus with 9 samples.

How the data were processed

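The measurement was bulk RNA sequencing of neutrophils from bone marrow of wild type C57/B6 mice, kept for 12 h in medium with 0.5% fetal bovine serum, alone or with cells named PyMT-N or PyMT-M. Per the labels, the neutrophils of both co-cultures were recovered by fluorescence-activated sorting. The labels do not say whether the neutrophils kept alone went through the sorter, so sorting and co-culture cannot be separated in either comparison with them. RNA was isolated with RNeasy Micro columns, and libraries were made from 150 pg of RNA with the QIAseq FX Single Cell RNA kit, per the labels' protocols. What N and M abbreviate is not given in the sources used here. Other samples of the series were not used here.

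The deposited values were raw read counts per Ensembl gene, which the authors made by aligning reads with STAR to mouse genome builds named GRCm38 and mm10, per the submitters' processing notes. All values were whole numbers with no normalisation. The counting tool, annotation release and strand setting are not given in the sources used here, so counts of near-identical, overlapping and antisense genes are uncertain. The table held 54532 Ensembl identifiers, 54409 with a symbol and 123 without. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which covered 12010 of the tested genes. Library totals ran from 1641049 to 4524563 counts, so that 1 CPM, counts scaled to the library total, stood for 1.64 to 4.52 counts. A floor of 3 counts, the limit that a count of 0 allows, was 0.573 to 2.26 normalised CPM by library.

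Genes were filtered with filterByExpr of edgeR 4.0.16 (count minimum 10, total minimum 15), which left 12012 genes, and scaled by the trimmed mean of M values (TMM). All 9 libraries entered a single model with a mean per group. The 3 groups of 3 were compared with the quasi-likelihood F test of edgeR, with robust moderation on and legacy estimation off, in R 4.3.3. Benjamini-Hochberg adjustment ran over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. SE is the fold change divided by the square root of F. Comparisons were PyMT-N co-culture with alone, PyMT-M co-culture with alone, and PyMT-N with PyMT-M co-culture. Overlap between the first pair was set against independent lists and against 20 simulations of unchanged groups. Genes whose groups did not overlap made up 56.7%, 57.9% and 52.9% of those tested in that order, where chance gives 10%.

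Gene lists, 24 of pathways and 9 of cell type markers, were fixed before the data were examined, as were the design, the threshold and all alternatives except those named below as later. The 30 lists with at least 5 tested genes were tested with camera of limma 3.58.1, with a preset correlation of 0.01. A correlation estimated from the data and fry were the alternatives. Called members were counted by the adjustment over all genes and by one over the list alone. Marker shares were compared by exact permutation of the 6 libraries, with a smallest two-sided p of 0.1. Erythroid, T and NK cell, and endothelial and platelet markers had too few tested genes for camera and were compared by share of counts only.

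Genes were named by a fixed rule. Its first part took, per comparison, the 6 largest rises and falls with an adjusted p under 0.05, a mean log2 CPM of at least 4, groups that did not overlap and a symbol that is not a predicted gene model. Its second part took, from each list with at least 3 called members or a camera call, up to 3 members of smallest p in the majority direction and 1 in the other. The third part named S100a8, S100a9, Csf3r, Cxcr2, Cxcl2, Il1b, Arg1, Cd274, Vegfa, Itgam, Itgb2, Cd44, Icam1, Epcam, Krt8, Krt18 and Col1a1 always, where values were worth a sentence. Genes repeated from another comparison, the test genes of the closing paragraphs and Tfrc stand outside the rule, and some genes that met it are not reported here.

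Other size factors were tried (relative log expression, upper quartile, library totals), as were no filter and a filter of at least 50 counts in 3 libraries. Other fits used DESeq2 1.42.0, limma-voom with sample weights, edgeR without robust moderation and with legacy estimation, a fit of only the compared groups, and the replicate number as a block. The threshold was also set to 0.01 or joined with an absolute log2 fold change of at least 1, and each library was left out in turn. Added after tumour-type transcripts had been seen were scaling to 25 pan-leukocyte genes, a limit to genes of at least 10 CPM alone, and both together.

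The code was tested on simulated data before use, with 50 genes changed at each of 4 fold sizes among 11607, 11596 and 11670 genes in the order of the comparisons. At 1.5, 2, 4 and 8-fold edgeR called 0%, 8%, 56% and 92% of them for the first, 0%, 18%, 70% and 82% for the second and 2%, 18%, 80% and 84% for the third, with 5, 5 and 11 unchanged genes called. Camera called a changed list of 20 genes in each and 0 of 20 unchanged lists. Small changes can therefore be missed.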

Results

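RNA of neutrophils from the bone marrow of wild type C57/B6 mice was sequenced after 12 h in medium with 0.5% fetal bovine serum. The cells had been kept alone or together with cells named PyMT-N or PyMT-M; PyMT, polyoma middle T antigen, drives a widely used mouse model of mammary carcinoma. Each of the 3 conditions had 3 libraries, and the neutrophils of both co-cultures were recovered by fluorescence-activated sorting. The alone libraries held 2698984, 3180382 and 1641049 counts, the PyMT-M libraries 4004235, 4307585 and 3269332 and the PyMT-N libraries 3552190, 3507969 and 4524563. Between 11814 and 17008 genes had a count, with the fewest in alone replicate 3. That library also had the highest share of counts in mitochondrial messenger RNA, 1.75%, against 0.235% and 0.180% in the other alone libraries. Of its counts 12.7% were mt-Rnr2, a mitochondrial ribosomal RNA, against 11.1% in PyMT-M replicate 3. Counts in ribosomal protein genes were 3.08% ± 0.164 (SD, n = 3) in PyMT-M co-culture, 1.86% ± 0.215 in PyMT-N co-culture and 1.46% ± 0.237 alone. The mt-Rnr2 share was lower in every PyMT-N library than in any other, at 3.12% ± 0.767 against 8.14% ± 2.59 with PyMT-M cells and 8.66% ± 3.55 alone, so this share differed along with PyMT-N co-culture.

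The groups separated on the first principal components, which held 54.6% and 26.0% of the variance of log2 CPM. The third, with 10.8%, set alone replicate 3 apart from all other libraries. Correlations of log2 CPM across genes lay between 0.881 and 0.968 within groups and between 0.654 and 0.778 across groups, where genes are not independent replicates. Library pairs of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 6.08.

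**Figure D1:**
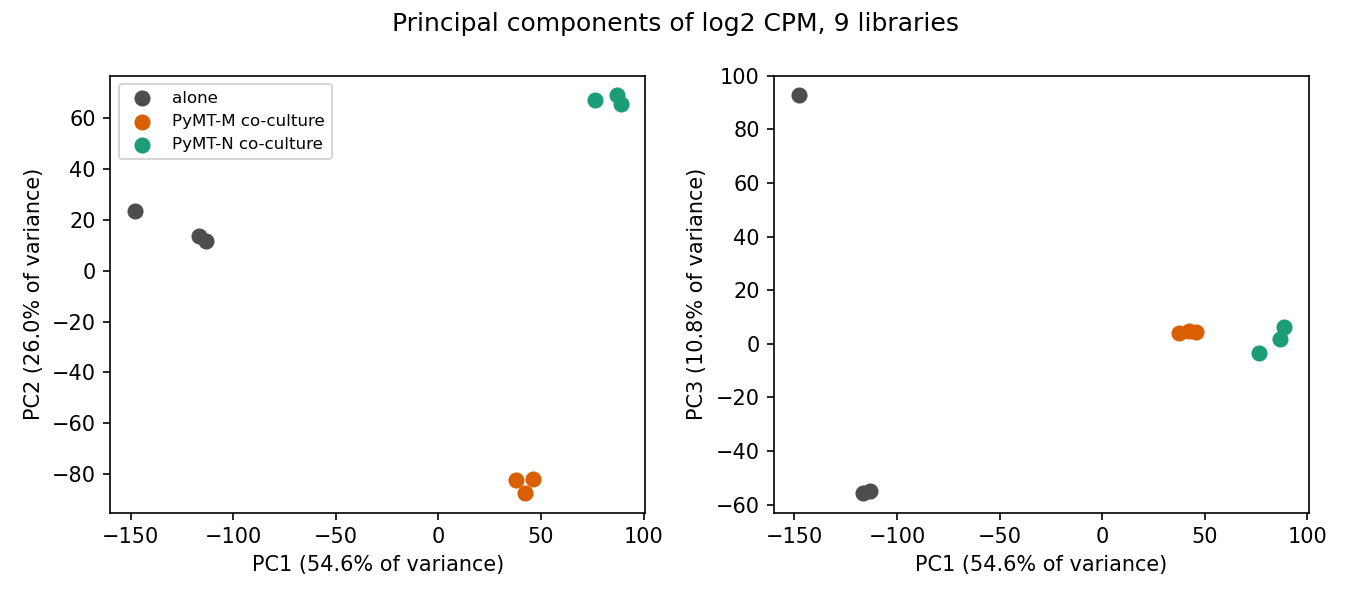
Principal components of log2 CPM for the 9 libraries, coloured by culture condition; the left panel plots the first component against the second and the right panel against the third. The 3 groups lie apart on the left, and alone replicate 3 stands alone on the third component, which holds 10.8% of the variance.

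The sorted co-culture libraries carried transcripts typical of other cell types, in a pattern that differed between the co-cultures. Epithelial marker genes held 3065 ± 504 CPM (SD, n = 3) in PyMT-N co-culture, 136 ± 21.1 in PyMT-M co-culture and 89.4 ± 26.7 alone. Mesenchymal marker genes held 2352 ± 251 CPM in PyMT-M co-culture, 1009.5 ± 107 in PyMT-N co-culture and 194 ± 15.9 alone. Markers of other marrow cells moved the opposite way: B cell genes went from 744 ± 428 CPM alone to 118 ± 28.9 with PyMT-M and 20.7 ± 2.52 with PyMT-N cells. Eosinophil and basophil genes went from 216 ± 25.1 to 11.8 ± 1.85 and 17.5 ± 5.15 CPM in the same order. Dendritic cell genes went from 611 ± 206 to 124 ± 17.5 and 137 ± 2.14, and monocyte and macrophage genes went from 2573 ± 257 to 1379 ± 107 and 1307 ± 163. T and NK cell genes stayed low, at 13.5 ± 2.22, 20.3 ± 1.51 and 6.60 ± 1.38 CPM, and endothelial and platelet genes lay at 64.3 ± 47.2, 11 ± 4.99 and 44.7 ± 17.0. The erythroid list went from 39.2 ± 10.4 to 270.0 ± 53.2 and 333 ± 73.6 CPM. Its transferrin receptor Tfrc, singled out after its values were seen, had a normalised CPM of 42.0 ± 11.9 alone, 228 ± 38.9 with PyMT-M and 324 ± 64.2 with PyMT-N cells. Where all 3 libraries of one group lay above all 3 of the other, the two-sided exact permutation p was 0.1, the smallest this design allows (Benjamini-Hochberg value over 27 comparisons 0.123). PyMT-N and PyMT-M co-cultures overlapped for monocyte and macrophage (exact p = 0.6), dendritic (0.4), erythroid (0.2) and eosinophil and basophil markers (0.2), as did PyMT-N co-culture and alone for endothelial and platelet markers (0.7).

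**Figure D2:**
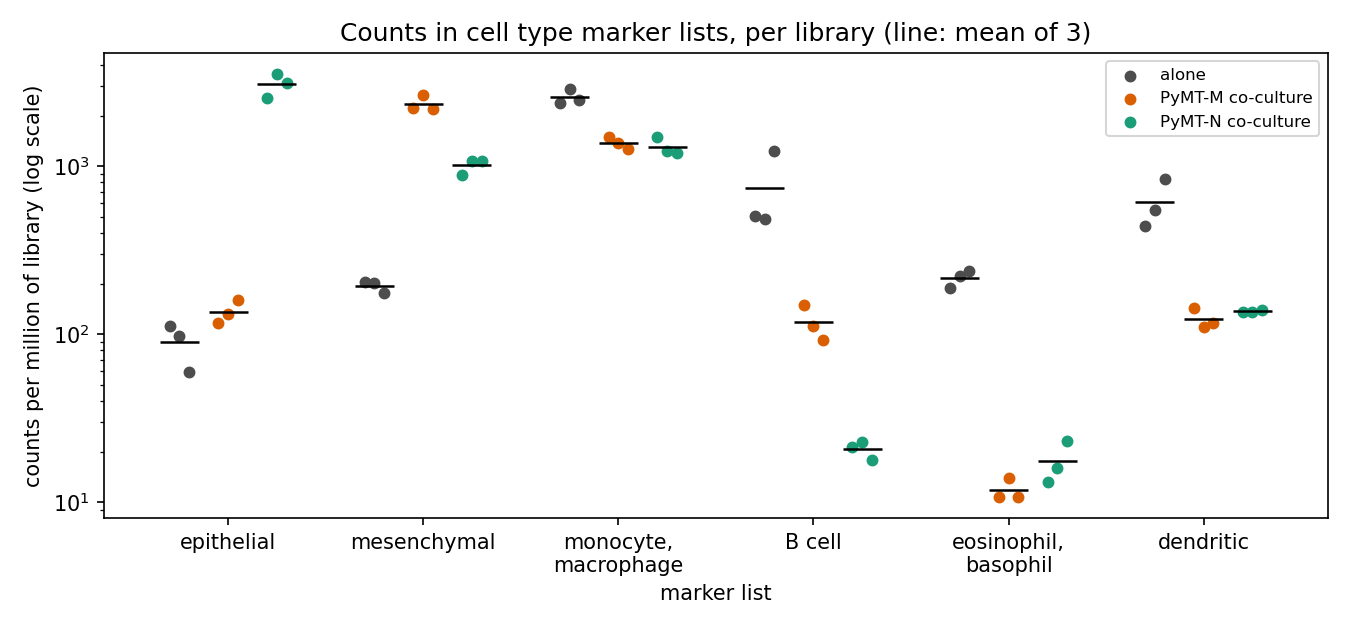
CPM of library, on a log scale, summed over 6 cell type marker lists; points are single libraries and lines are means of 3. Epithelial markers average 3065 CPM in PyMT-N co-culture against 89.4 alone, and mesenchymal markers average 2352 CPM in PyMT-M co-culture against 194 alone.

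Because added transcripts lower the share of all others, directions below hold for trimmed-mean scaling unless another scaling is named. Against it, scaling by library totals moved the median log2 fold change of all genes by 0.29 for PyMT-N against alone, 0.47 for PyMT-M against alone and -0.21 for PyMT-N against PyMT-M. Scaling to pan-leukocyte genes, a choice made after the marker counts were seen, moved it by 1.40, 1.64 and -0.27 in that order. That scaling rests on 24 tested genes whose own log2 fold changes had a median of -1.31 (SD 0.76), -1.70 (SD 0.41) and 0.19 (SD 0.69). Gene values below are log2 fold changes ± SE, with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test and 3 libraries per group. A gene without counts in a group is given as at least a fold, set against a floor of 3 counts over the group, and a gene with 1 to 3 counts there as a ratio with its 95% counting interval. Such intervals and floors cover counting error only. The p-values reflect the spread between these libraries, since the labels call the libraries biological replicates without tying them to separate animals.

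The first comparison asked how 12 h with PyMT-N cells changed the neutrophil transcriptome relative to culture alone. Interferon-stimulated and cytokine genes rose together, primary granule genes fell, and epithelial transcripts appeared. The antiviral genes Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731, GRCm38) and Rsad2 rose from 7.35 ± 1.66 to 1159.8 ± 152 and from 46.0 ± 24.9 to 5501 ± 351 normalised CPM (SD, n = 3). Slfn4, a myeloid schlafen gene, reached 30136 ± 3031 CPM from 2201 ± 207. Lactoferrin, Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), dropped from 1954 ± 423 to 44.5 ± 11.1 CPM. Of 12012 genes tested, 3533 were higher and 2831 lower in PyMT-N co-culture. Library totals gave 4315 higher and 2112 lower and leukocyte scaling 7883 higher and 615 lower. Among the 7295 genes of at least 10 CPM alone, 1375 higher and 2557 lower were called, and 4380 higher and 524 lower with leukocyte scaling.

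Among the largest rises under the naming rule were genes of adherent cells. Tead1, a transcription factor of the Hippo pathway, was at least 240.5-fold higher (adjusted p = 1.88e-07), and Aebp1, an extracellular matrix protein gene, at least 118-fold higher (adjusted p = 2.69e-07). Counts of the keratin gene Krt8 stood at a 2374-fold ratio, interval 426 to 93775 (adjusted p = 2.28e-10). The matricellular gene Ccn1 reached a 1634-fold ratio, interval 293 to 64573 (adjusted p = 9.07e-10), and the epithelial secretory gene Wfdc2 a 1048-fold ratio, interval 290.0 to 8658 (adjusted p = 8.92e-10). Of 21 tested epithelial markers, 20 were higher and none lower (camera adjusted p = 4.30e-23 and adjusted p = 0.0211 with an estimated correlation). Krt18 (8.94 ± 0.45), the tight junction gene Cldn7 (a 1011-fold ratio, interval 279.8 to 8354) and the adhesion molecule gene Epcam (at least 396-fold) were among them, each with an adjusted p of at most 1.19e-08. Mesenchymal markers had 12 higher, 2 lower and 8 not past the threshold among 22 tested (camera adjusted p = 8.27e-04 and adjusted p = 0.101 with an estimated correlation). Cald1 (7.73 ± 0.29), which binds actin, the caveolin gene Cav1 (a 601-fold ratio, interval 166 to 4963) and Sparc (a 425-fold ratio, interval 76.1 to 16825) were higher, each with an adjusted p of at most 1.44e-07. The collagen gene Col1a1 (-2.95 ± 0.83, adjusted p = 0.00597) and the transcription factor Zeb1 (-1.73 ± 0.33, adjusted p = 4.61e-04) were lower. Col1a1 was not past the threshold without alone replicate 1 (-2.07, adjusted p = 0.094). With leukocyte scaling neither was past it (-1.57 and -0.32, adjusted p = 0.132 and 0.49).

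All 36 tested interferon-stimulated genes were higher (camera adjusted p = 9.56e-46 and adjusted p = 0.0211 with an estimated correlation). Ifit3 (7.32 ± 0.24), Slfn4 (3.78 ± 0.14) and Rsad2 (6.99 ± 0.29) had the smallest p, each with an adjusted p of at most 9.84e-11. Of 30 chemokine and cytokine genes, 27 were higher and 1 lower (camera adjusted p = 5.74e-16 and adjusted p = 0.0211 with an estimated correlation). Il1a (8.78 ± 0.50), the T cell attractant Cxcl10 (8.03 ± 0.34), Lif (a 2385-fold ratio, interval 428 to 94216), the neutrophil attractant Cxcl2 (5.66 ± 0.59) and Il1b (1.76 ± 0.25) were higher, each with an adjusted p of at most 3.83e-05. The list moved with the epithelial markers, and tumour cell RNA was not excluded as a source. Il1a (0.62 CPM alone, 0.13 with PyMT-M and 366 with PyMT-N cells) and Lif (0.15, 0.96 and 381) had the profile of Krt18 (0.70, 0.13 and 332). Il1b, at 536 CPM alone, did not. Tgfb1 fell (-1.02 ± 0.23, adjusted p = 0.00176) but stood at 0.35 with leukocyte scaling. The angiogenic factor gene Vegfa (0.75 ± 0.29, adjusted p = 0.0422) kept its call only when alone replicate 2 was the library left out, with 0.46 (adjusted p = 0.0621) without alone replicate 3 and 0.71 (adjusted p = 0.0986) without PyMT-N replicate 1. It was lost as well with the stricter filter (0.70), the legacy option of edgeR (0.80) or a fit of the compared groups only (0.74). Genes described in tumour-associated neutrophils had 21 higher, 2 lower and 2 not past the threshold among 25 tested (camera adjusted p = 1.77e-06 and adjusted p = 0.0221 with an estimated correlation). Spp1, the osteopontin gene (3.90 ± 0.20), Il1rn, the interleukin-1 antagonist (4.25 ± 0.26), Wfdc17 (3.86 ± 0.27), arginase Arg1 (7.82 ± 0.70) and the PD-L1 gene Cd274 (3.25 ± 0.27) rose, each with an adjusted p of at most 1.59e-07. This list moved with the epithelial markers too. The SLAM family receptor gene Cd84 fell (-1.38 ± 0.17, adjusted p = 9.37e-06), with 0.028 under leukocyte scaling.

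TGF-beta response genes had 16 higher, 1 lower and 2 not past the threshold among 19 tested (camera adjusted p = 1.47e-08 and adjusted p = 0.0191 with an estimated correlation). Thbs1, which like Ccn1 encodes a matricellular protein, stood at 4.36 ± 0.27, adjusted p = 6.87e-09. The list moved with the epithelial markers. NF-kB targets had 16 higher, 5 lower and 5 not past the threshold among 26 tested (camera adjusted p = 0.0241 and adjusted p = 0.448 with an estimated correlation). The cyclooxygenase gene Ptgs2 (4.80 ± 0.29), Ier3 (2.74 ± 0.18) and the adhesion ligand gene Icam1 (2.02 ± 0.36) were higher, each with an adjusted p of at most 2.65e-04. Survival and apoptosis regulators had 13 higher, 3 lower and 12 not past the threshold among 28 tested (camera adjusted p = 0.0121 and adjusted p = 0.203 with an estimated correlation). The anti-apoptotic genes Bcl2l1 (3.69 ± 0.23, adjusted p = 8.91e-09) and Bcl2a1a (6.40 ± 0.51, adjusted p = 2.39e-08) were higher. Bcl2a1a is one of several near-identical copies among which reads can be split. Proteases and inhibitors had 12 higher, 4 lower and 12 not past the threshold among 28 tested (camera adjusted p = 0.00589 and adjusted p = 0.0523 with an estimated correlation). Serpinb2 (8.27 ± 0.41, adjusted p = 6.50e-11) and cathepsin L, Ctsl (3.23 ± 0.18, adjusted p = 2.18e-09), were higher. Serpinb2 too had the profile of Krt18 (1.17 CPM alone, 1.40 with PyMT-M and 358 with PyMT-N cells). Ctsl, at 111 CPM alone, did not. Immediate early and heat shock genes, which handling and sorting can also induce, had 19 higher, 3 lower and 9 not past the threshold among 31 tested (camera adjusted p = 5.07e-05 and adjusted p = 0.0562 with an estimated correlation). Myc (6.66 ± 0.34, adjusted p = 7.69e-10) and Hsp90aa1 (2.63 ± 0.20, adjusted p = 6.50e-08) rose. Cell cycle genes had 28 higher, 1 lower and 6 not past the threshold among 35 tested (camera adjusted p = 2.12e-05 and adjusted p = 0.0523 with an estimated correlation). Cdk1 (4.15 ± 0.34, adjusted p = 1.51e-07) rose, and the list moved with the epithelial markers. Sterol synthesis genes had 20 higher, 1 lower and 5 not past the threshold among 26 tested (camera adjusted p = 3.50e-04 and adjusted p = 0.0221 with an estimated correlation). Sc5d (2.24 ± 0.23, adjusted p = 1.17e-06) and Dhcr7 (3.19 ± 0.35, adjusted p = 2.54e-06) were higher.

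Among the largest falls under the naming rule were the sodium channel subunit gene Scnn1a (-6.62 ± 0.38), the cation channel gene Trpm2 (-6.46 ± 0.24) and the immunoglobulin heavy chain gene Ighm (-5.70 ± 0.34), each with an adjusted p of at most 5.48e-09. The lymphocyte receptor gene Ly9 (-5.64 ± 0.77), the tyrosine kinase gene Bmx (-5.49 ± 0.52) and Prss34 (-5.79 ± 0.34), a serine protease gene of basophils and mast cells, fell too, each with an adjusted p of at most 7.47e-05. Of 10 primary granule genes, 9 were lower (camera adjusted p = 2.16e-05 and adjusted p = 0.0221 with an estimated correlation). The myeloperoxidase gene Mpo (at least 206-fold lower), Gstm1 (-3.82 ± 0.29) and the ficolin gene Fcnb (-6.57 ± 0.78) fell, each with an adjusted p of at most 1.42e-06. Ctsc, which activates granule proteases, rose (1.79 ± 0.20, adjusted p = 3.74e-06). Secondary and tertiary granule genes had 1 higher, 10 lower and 5 not past the threshold among 16 tested (camera adjusted p = 6.08e-07 and adjusted p = 0.0738 with an estimated correlation). Lyz2, lysozyme (-3.06 ± 0.16), Ltf (-5.46 ± 0.30) and Ngp (-4.23 ± 0.25) fell and Wfdc21 rose (1.10 ± 0.21), each with an adjusted p of at most 4.11e-04. With leukocyte scaling the primary granule list had 1 higher and 8 lower, and the secondary and tertiary granule list then had 6 higher and 7 lower. Markers of other marrow cells fell alongside. B cell markers were lower for 8 of 8 (camera adjusted p = 6.92e-05 and adjusted p = 0.181 with an estimated correlation). Eosinophil and basophil markers were lower for 5 of 5 (camera adjusted p = 1.99e-05 and adjusted p = 0.0211 with an estimated correlation). Dendritic cell markers were lower for 9 of 11 and higher for 1 (camera adjusted p = 1.66e-05 and adjusted p = 0.0733 with an estimated correlation). The mast cell protease gene Cpa3 (-7.32 ± 0.55, adjusted p = 3.63e-09) and the class II gene H2-Aa (-5.66 ± 0.45, adjusted p = 1.02e-07) were among them. Bst2, also interferon-induced, rose (3.10 ± 0.32, adjusted p = 1.61e-06).

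Neutrophil identity genes had 3 higher, 10 lower and 6 not past the threshold among 19 tested, against 12 higher and 1 lower with leukocyte scaling (camera adjusted p = 0.0402 and adjusted p = 0.546 with an estimated correlation). The resistin-like gene Retnlg (-4.39 ± 0.26), the calprotectin gene S100a8 (-1.53 ± 0.18) and the surface receptor gene Cd177 (-1.64 ± 0.20) were lower, each with an adjusted p of at most 6.11e-06. The interleukin-1 decoy receptor gene Il1r2 rose (4.16 ± 0.24, adjusted p = 4.12e-09). S100a9 (-1.23 ± 0.16, adjusted p = 1.47e-05), the G-CSF receptor gene Csf3r (-0.79 ± 0.16, adjusted p = 8.19e-04), the chemokine receptor gene Cxcr2 (-0.46 ± 0.16, adjusted p = 0.025) and the integrin gene Itgam (-0.65 ± 0.25, adjusted p = 0.036) were lower by trimmed-mean scaling and stood at 0.17, 0.60, 0.92 and 0.74 with leukocyte scaling. The calls of Cxcr2 and Itgam were lost without alone replicate 1 (-0.36 and -0.43, adjusted p = 0.109 and 0.194), without alone replicate 2 (-0.45 and -0.56) and without PyMT-N replicate 2 (-0.35 and -0.62) or 3 (-0.43 and -0.57). Library totals ended both calls too (-0.17 and -0.37, adjusted p = 0.391 and 0.225). That of Itgam was also lost with DESeq2 (-0.59), the legacy option of edgeR (-0.64) or a fit of the compared groups only (-0.66), and without PyMT-M replicate 1 (-0.64), PyMT-M replicate 2 (-0.64) or PyMT-N replicate 1 (-0.72). Adhesion genes had 9 higher, 14 lower and 8 not past the threshold among 31 tested, against 16 higher and 7 lower with leukocyte scaling (camera adjusted p = 0.0701 and adjusted p = 0.464 with an estimated correlation). In that list the hyaluronan receptor gene Cd44 rose (1.29 ± 0.17, adjusted p = 1.46e-05) and the integrin gene Itgb2 fell (-1.68 ± 0.20, adjusted p = 7.16e-06). NADPH oxidase genes had 0 higher, 7 lower and 1 not past the threshold among 8 tested, and 4 higher and 1 lower with leukocyte scaling (camera adjusted p = 2.98e-04 and adjusted p = 0.0733 with an estimated correlation). The catalytic subunit gene Cybb stood at -2.77 ± 0.21, adjusted p = 5.15e-08. Oxidative stress genes had 1 higher, 15 lower and 6 not past the threshold among 22 tested, and 11 higher and 3 lower with leukocyte scaling (camera adjusted p = 9.57e-05 and adjusted p = 0.181 with an estimated correlation). Catalase, Cat, stood at -2.96 ± 0.20, adjusted p = 2.15e-08.

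Further lists passed the set test. Hypoxia response genes had 14 higher and 4 lower of 23 (camera adjusted p = 0.00598 and adjusted p = 0.0808 with an estimated correlation). Unfolded protein response genes had 13 higher and 2 lower of 25 (camera adjusted p = 0.0203 and adjusted p = 0.0733 with an estimated correlation). Monocyte and macrophage markers had 2 higher and 11 lower of 16 (camera adjusted p = 0.00367 and adjusted p = 0.265 with an estimated correlation). The others did not pass it. Glycolysis genes had 13 higher and 5 lower of 22 (camera adjusted p = 0.407). Respiratory chain genes had 8 higher and 7 lower of 47 (camera adjusted p = 0.736). Lipid storage and uptake genes had 7 higher and 10 lower of 25, and 13 higher and 4 lower with leukocyte scaling (camera adjusted p = 0.375). Antigen presentation genes had 9 higher and 9 lower of 24, and 15 higher and 6 lower with leukocyte scaling (camera adjusted p = 0.411). Pattern recognition and Fc receptors had 6 higher and 9 lower of 30, and 21 higher and 3 lower with leukocyte scaling (camera adjusted p = 0.455). Chemoattractant and growth factor receptors had 9 higher and 12 lower of 33, and 22 higher and 4 lower with leukocyte scaling (camera adjusted p = 0.221). The median fold change, the mean and the set test did not all point the same way for respiratory chain, lipid and antigen presentation genes. Adjusted over the list alone, 11 lists had other numbers of higher and lower genes. These were 18 and 5 for NF-kB targets, 10 and 15 for adhesion, 14 and 6 for glycolysis and 8 and 6 for respiratory chain subunits. These were 21 and 1 for cholesterol synthesis, 14 and 3 for survival and apoptosis, 22 and 3 for immediate early and heat shock genes and 10 and 10 for antigen presentation. These were 10 and 12 for chemoattractant and growth factor receptors, 12 and 3 for mesenchymal markers and 1 and 10 for dendritic cell markers. With the preset correlation 23 of 30 lists were called and 8 with an estimated one. Mixed splits, which keep part of the group difference, gave up to 19 calls with the former, and sorting was confounded with co-culture.

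The same question was asked for PyMT-M cells. Interferon-stimulated genes rose here too, mesenchymal rather than epithelial markers rose as a group, and cytokine genes did not pass the set test in either direction. Ifit3 went from 7.35 ± 1.66 to 704 ± 41.1 CPM (SD, n = 3) and Slfn4 from 2201 ± 207 to 13498 ± 416. The collagen gene Col3a1 went from 0.273 ± 0.239 to 233 ± 46.1 CPM. Of 12012 genes, 3382 were higher and 3353 lower than alone. Library totals gave 4571 higher and 1913 lower and leukocyte scaling 8184 higher and 184 lower. Among the 7295 genes of at least 10 CPM alone, 1192 higher and 3037 lower were called, and 4707 higher and 145 lower with leukocyte scaling.

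Aebp1 was at least 280.4-fold higher (adjusted p = 6.18e-08) and Tead1 at least 146-fold higher (adjusted p = 1.25e-06). Counts of the collagen chaperone gene Serpinh1 stood at a 3225-fold ratio, interval 579 to 127399 (adjusted p = 1.03e-09). Sparc, a matricellular gene, had a 2314-fold ratio, interval 415 to 91405 (adjusted p = 6.02e-09), and the phosphatase gene Dusp9 a 2211-fold ratio, interval 397 to 87337 (adjusted p = 1.18e-08). Yap1, the Hippo pathway co-activator, rose by 10.03 ± 0.41, adjusted p = 5.59e-11. Mesenchymal markers had 17 higher, 1 lower and 4 not past the threshold among 22 tested (camera adjusted p = 7.59e-14 and adjusted p = 0.0301 with an estimated correlation). Cald1 (6.19 ± 0.31), Col3a1 (a 714-fold ratio, interval 197 to 5899) and Col1a1 (2.69 ± 0.43) were higher, each with an adjusted p of at most 7.48e-05. Smooth muscle actin, Acta2, was lower (-0.95 ± 0.29, adjusted p = 0.0112), with 0.72 under leukocyte scaling and a call lost with library totals (-0.43, adjusted p = 0.225). Epithelial markers had 3 higher, 2 lower and 16 not past the threshold among 21 tested (camera adjusted p = 0.986 and adjusted p = 0.992 with an estimated correlation). Krt8 stood at a 272-fold ratio, interval 48.7 to 10775 (adjusted p = 2.09e-07). Epcam was at least 4.0-fold higher (adjusted p = 0.0196), a call lost without alone replicate 1 or 2 (adjusted p = 0.051 and 0.0648). Cadherin 1, Cdh1, fell (-4.10 ± 0.64, adjusted p = 4.80e-05). Krt18 was near absent in both groups, with 0.127 ± 0.220 and 0.697 ± 0.670 CPM (adjusted p = 0.306).

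Of 36 interferon-stimulated genes, 34 were higher and none lower (camera adjusted p = 8.23e-28 and adjusted p = 0.0301 with an estimated correlation). Ifit3 (6.60 ± 0.24), Rsad2 (5.41 ± 0.27) and Slfn4 (2.62 ± 0.13) led them by p, each with an adjusted p of at most 3.86e-09. Cell cycle genes had 31 higher, 0 lower and 4 not past the threshold among 35 tested (camera adjusted p = 6.72e-14 and adjusted p = 0.0301 with an estimated correlation). Cdk1 (4.04 ± 0.34), the spindle gene Tpx2 (3.46 ± 0.30) and the topoisomerase gene Top2a (2.56 ± 0.22) rose, each with an adjusted p of at most 5.09e-07. The list moved with the mesenchymal markers. Sterol synthesis genes had 11 higher, 2 lower and 13 not past the threshold among 26 tested (camera adjusted p = 0.0184 and adjusted p = 0.0887 with an estimated correlation). Immediate early and heat shock genes had 12 higher, 6 lower and 13 not past the threshold among 31 tested (camera adjusted p = 0.0155 and adjusted p = 0.166 with an estimated correlation). Myc (7.03 ± 0.34, adjusted p = 1.36e-09) and Hsp90ab1 (2.14 ± 0.15, adjusted p = 5.89e-08) rose. Chemokine and cytokine genes had 6 higher, 7 lower and 17 not past the threshold among 30 tested, against 7 higher and 3 lower with library totals and 16 higher and 0 lower with leukocyte scaling (camera adjusted p = 0.73 and adjusted p = 0.847 with an estimated correlation). The monocyte attractant Ccl2 rose (7.64 ± 0.49, adjusted p = 8.35e-09). Ccl6 fell (-2.05 ± 0.17, adjusted p = 3.64e-07), as did Ccl3 (-1.26 ± 0.22, adjusted p = 2.56e-04), which stood at 0.40 with leukocyte scaling. Cxcl2 had 0.14 ± 0.59 (adjusted p = 0.854) and 1.80 (adjusted p = 0.0147) with leukocyte scaling. Il1b had -0.62 ± 0.25 (adjusted p = 0.0454) but 1.04 with leukocyte scaling. Its call was lost without alone replicate 1 (-0.63, adjusted p = 0.079) or 3 (-0.49), PyMT-M replicate 1 (-0.61) or 3 (-0.36, adjusted p = 0.199), and PyMT-N replicate 1 (-0.60) or 3 (-0.61). It was lost as well with RLE (-0.53, adjusted p = 0.104) or upper quartile size factors (-0.53), library totals (-0.099), DESeq2 (-0.53), limma-voom (-0.45), the legacy option of edgeR (-0.62) or a fit of the compared groups only (-0.50), so a fall was not upheld. Cd274 rose (0.94 ± 0.29, adjusted p = 0.0131), except without alone replicate 2 (0.62, adjusted p = 0.105). Arg1 (0.15 ± 1.71, adjusted p = 0.95) and Vegfa (0.14 ± 0.30, adjusted p = 0.706) were not past the threshold, though Vegfa was with leukocyte scaling (1.82).

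Under the naming rule the largest falls were in Prss34 (-5.34 ± 0.31), the fibronectin gene Fn1 (-4.47 ± 1.01) and the corepressor gene Tle4 (-4.40 ± 0.99), each with an adjusted p of at most 0.00389. Other large falls were in the invariant chain gene Cd74 (-4.27 ± 0.32), Csf2rb2 (-3.93 ± 0.27), which encodes an interleukin-3 receptor chain near-identical to Csf2rb, and the B cell receptor-like gene Fcrl1 (-3.59 ± 0.39), each with an adjusted p of at most 3.04e-06. Fn1 and Tle4 varied widely alone, at 33.3 ± 37.3 and 341 ± 472 CPM. Primary granule genes had 0 higher, 9 lower and 1 not past the threshold among 10 tested, with 1 higher and 6 lower under leukocyte scaling (camera adjusted p = 2.04e-05 and adjusted p = 0.0627 with an estimated correlation). Mpo (-6.56 ± 0.56), Gstm1 (-3.16 ± 0.28) and the proteinase gene Prtn3 (-4.37 ± 0.51) fell, each with an adjusted p of at most 5.98e-06. Secondary and tertiary granule genes had 0 higher, 11 lower and 5 not past the threshold among 16 tested but 8 higher and 0 lower with leukocyte scaling (camera adjusted p = 2.00e-05 and adjusted p = 0.157 with an estimated correlation). Lyz2 (-1.79 ± 0.16, adjusted p = 5.49e-07) and the protease inhibitor gene Slpi (-1.73 ± 0.17, adjusted p = 1.80e-06) were lower. Neutrophil identity genes had 1 higher, 17 lower and 1 not past the threshold among 19 tested but 8 higher and 0 lower with leukocyte scaling (camera adjusted p = 2.79e-06 and adjusted p = 0.175 with an estimated correlation). The lectin gene Clec4d (-1.64 ± 0.17), the formyl peptide receptor gene Fpr1 (-1.74 ± 0.18) and the gelatinase gene Mmp9 (-1.81 ± 0.20) fell, each with an adjusted p of at most 3.57e-06. Il1r2 rose (0.78 ± 0.24, adjusted p = 0.0131), though not past the threshold without alone replicate 2 or PyMT-M replicate 2 (0.60 and 0.69, adjusted p = 0.0833 and 0.051). S100a8 (-1.38 ± 0.18, adjusted p = 1.95e-05), S100a9 (-1.19 ± 0.16, adjusted p = 2.24e-05), Csf3r (-1.40 ± 0.16, adjusted p = 7.11e-06) and Cxcr2 (-1.06 ± 0.16, adjusted p = 6.54e-05) fell by trimmed-mean scaling and stood at 0.31, 0.46, 0.26 and 0.60 with leukocyte scaling.

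Chemoattractant and growth factor receptors had 3 higher, 28 lower and 2 not past the threshold among 33 tested but 10 higher and 2 lower with leukocyte scaling (camera adjusted p = 3.20e-09 and adjusted p = 0.0662 with an estimated correlation). Adhesion genes had 3 higher, 23 lower and 5 not past the threshold among 31 tested but 10 higher and 4 lower with leukocyte scaling (camera adjusted p = 7.42e-06 and adjusted p = 0.151 with an estimated correlation). The integrin activator gene Fermt3 (-2.80 ± 0.27), the embigin gene Emb (-1.71 ± 0.18) and Itgb2 (-1.85 ± 0.21) fell, each with an adjusted p of at most 4.21e-06. Itgb1 rose (1.08 ± 0.18, adjusted p = 1.44e-04). Itgam (-1.65 ± 0.25, adjusted p = 7.35e-05) and Cd44 (-0.87 ± 0.17, adjusted p = 5.18e-04) were lower, and Icam1 had -0.77 ± 0.44 (adjusted p = 0.143). With leukocyte scaling the 3 genes stood at 0.025, 0.80 and 0.89. Oxidative stress genes had 1 higher, 20 lower and 1 not past the threshold among 22 tested but 8 higher and 4 lower with leukocyte scaling (camera adjusted p = 8.95e-10 and adjusted p = 0.0887 with an estimated correlation). Cat (-2.86 ± 0.20, adjusted p = 6.60e-08) and the ferritin gene Ftl1 (-2.0 ± 0.14, adjusted p = 6.60e-08) fell. B cell markers were lower in 7 of 8 (camera adjusted p = 1.28e-04 and adjusted p = 0.175 with an estimated correlation). Eosinophil and basophil markers fell in 5 of 5 (camera adjusted p = 2.66e-06 and adjusted p = 0.0301 with an estimated correlation). Dendritic cell markers fell in 9 of 11 (camera adjusted p = 8.30e-06 and adjusted p = 0.0791 with an estimated correlation). Ms4a1, which encodes CD20, had a 269-fold ratio, interval 73.6 to 2231, alone over co-culture (adjusted p = 3.86e-07). Cpa3 (-6.46 ± 0.48, adjusted p = 1.11e-08) and H2-Aa (-4.56 ± 0.39, adjusted p = 4.74e-07) fell.

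More lists passed here. NF-kB targets had 1 higher and 13 lower of 26, and 18 higher and 0 lower with leukocyte scaling (camera adjusted p = 0.0064 and adjusted p = 0.286 with an estimated correlation). Proteases and inhibitors had 4 higher and 15 lower of 28, and 12 higher and 0 lower with leukocyte scaling (camera adjusted p = 0.024 and adjusted p = 0.157 with an estimated correlation). NADPH oxidase genes had 0 higher and 8 lower of 8, and 2 higher and 0 lower with leukocyte scaling (camera adjusted p = 3.24e-06 and adjusted p = 0.0662 with an estimated correlation). Antigen presentation genes had 2 higher and 13 lower of 24, and 13 higher and 5 lower with leukocyte scaling (camera adjusted p = 0.00141 and adjusted p = 0.116 with an estimated correlation). Pattern recognition and Fc receptors had 4 higher and 21 lower of 30, and 14 higher and 2 lower with leukocyte scaling (camera adjusted p = 9.65e-05 and adjusted p = 0.151 with an estimated correlation). The rest did not pass. Tumour-associated neutrophil genes had 5 higher and 11 lower of 25, and 16 higher and 1 lower with leukocyte scaling (camera adjusted p = 0.198). Glycolysis genes had 6 higher and 9 lower of 22, and 16 higher and 0 lower with leukocyte scaling (camera adjusted p = 0.265). Lipid storage and uptake genes had 4 higher and 12 lower of 25, and 14 higher and 1 lower with leukocyte scaling (camera adjusted p = 0.098). Survival and apoptosis regulators had 3 higher and 9 lower of 28, and 23 higher and 0 lower with leukocyte scaling (camera adjusted p = 0.119). TGF-beta response genes had 5 higher and 7 lower of 19, and 13 higher and 0 lower with leukocyte scaling (camera adjusted p = 0.986). Hypoxia response genes had 9 higher and 7 lower of 23 (camera adjusted p = 0.386). Respiratory chain genes had 11 higher and 4 lower of 47 (camera adjusted p = 0.73). Unfolded protein response genes had 12 higher and 4 lower of 25 (camera adjusted p = 0.0876). Monocyte and macrophage markers had 5 higher and 8 lower of 16, and 8 higher and 4 lower with leukocyte scaling (camera adjusted p = 0.0982). The median fold change, the mean and the set test did not all point the same way for chemokine and cytokine, TGF-beta response, respiratory chain, tumour-associated neutrophil and epithelial genes. Adjusted over the list alone, 8 lists had other numbers of higher and lower genes. These were 6 and 6 for chemokines and cytokines, 4 and 16 for proteases and inhibitors, 9 and 8 for the hypoxia response and 8 and 3 for respiratory chain subunits. These were 3 and 13 for antigen presentation, 4 and 22 for pattern recognition and Fc receptors, 1 and 1 for epithelial markers and 0 and 8 for B cell markers. Under the preset correlation 19 of 30 lists were called and 4 with an estimated one. Mixed splits gave up to 17 list calls.

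**Figure D3:**
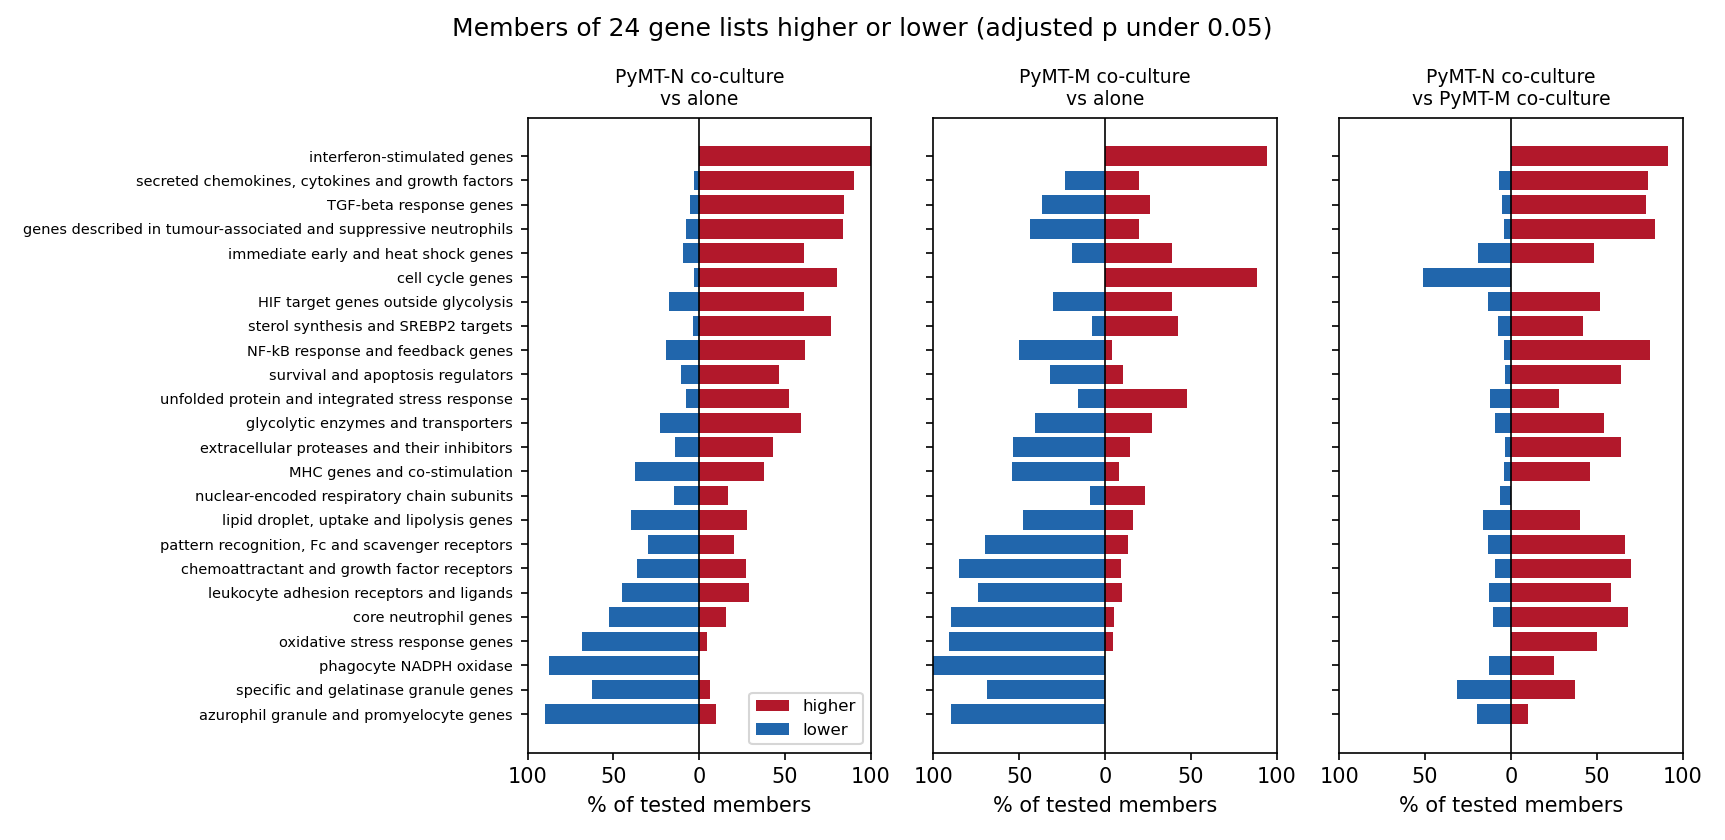
Percent of the tested members of 24 gene lists that were higher (to the right) or lower (to the left) at an adjusted p under 0.05, in the 3 comparisons, with trimmed-mean scaling. All 36 interferon-stimulated genes are higher in PyMT-N co-culture than alone, and several lists that point left in the middle panel, such as neutrophil identity, point right with leukocyte scaling.

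The comparison of the co-cultures asked what differed between neutrophils kept with PyMT-N and with PyMT-M cells, both sorted. Cytokine and interferon-stimulated gene lists were higher with PyMT-N cells, as were epithelial markers, and the mesenchymal marker list was lower. The chemokine gene Ccl6 (ENSMUSG00000018927, chromosome 11, 83587882 to 83593087) was at 3319 ± 338 CPM (SD, n = 3) with PyMT-N and 93.6 ± 0.254 with PyMT-M cells. Il1rn was at 6376 ± 234 against 345 ± 72.1 CPM, and Ltf at 44.5 ± 11.1 against 1514 ± 498. Of 12012 genes, 2297 were higher and 1865 lower in PyMT-N co-culture. Library totals gave 1834 higher and 2703 lower and leukocyte scaling 1589 higher and 2569 lower. Among the 7295 genes of at least 10 CPM alone, 1235 higher and 917 lower were called, and 680 higher and 1302 lower with leukocyte scaling.

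Fibronectin, Fn1 (9.43 ± 0.81), Thbs1 (6.41 ± 0.30) and Csf2rb2 (5.97 ± 0.26) had the largest rises over PyMT-M under the naming rule, each with an adjusted p of at most 6.25e-06. Ptgs2 (5.86 ± 0.30), Cxcl2 (5.52 ± 0.56) and Ccl6 (5.15 ± 0.19) came next, each with an adjusted p of at most 3.51e-05. Under that rule the largest falls were in the cathelicidin gene Camp (-5.83 ± 0.56), Ltf (-5.09 ± 0.29) and Scnn1a (-5.03 ± 0.39), each with an adjusted p of at most 8.63e-06. The zinc finger gene Zcchc24 (-4.98 ± 0.32), Trpm2 (-4.56 ± 0.24) and the lipoprotein lipase gene Lpl (-4.48 ± 0.34) followed, each with an adjusted p of at most 1.75e-07. All 21 epithelial markers were higher (camera adjusted p = 2.06e-50 and adjusted p = 0.00209 with an estimated correlation). Krt18 stood at a 2264-fold ratio, interval 626 to 18701 (adjusted p = 6.81e-12). Cldn7 (9.01 ± 0.43), Cdh1 (8.52 ± 0.42), Epcam (6.62 ± 0.34) and Krt8 (3.12 ± 0.20) were also higher, each with an adjusted p of at most 2.57e-08. Mesenchymal markers had 5 higher, 14 lower and 3 not past the threshold among 22 tested (camera adjusted p = 4.51e-07 and adjusted p = 0.019 with an estimated correlation). Col3a1 was at least 915-fold lower (adjusted p = 5.56e-10) and Col6a1 at least 553-fold lower (adjusted p = 1.97e-08). Fstl1 (-6.51 ± 0.48) and Col1a1 (-5.64 ± 0.54) were lower too, while Cald1 was higher (1.53 ± 0.16), each with an adjusted p of at most 2.39e-06.

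Chemokine and cytokine genes had 24 higher, 2 lower and 4 not past the threshold among 30 tested (camera adjusted p = 3.39e-28 and adjusted p = 8.90e-04 with an estimated correlation). Il1a stood at a 2541-fold ratio, interval 703 to 20991 (adjusted p = 1.72e-11). Lif (8.70 ± 0.36) and Il1b (2.37 ± 0.26) were higher, and Ccl7, a monocyte attractant, was lower (-1.86 ± 0.24), each with an adjusted p of at most 1.21e-05. The list moved with the epithelial markers, and tumour cell RNA was not excluded as a source. Vegfa had 0.61 ± 0.27 (adjusted p = 0.1), past the threshold without alone replicate 3 (0.60, adjusted p = 0.00686), with limma-voom (0.57, adjusted p = 0.0125) or in a fit of the compared groups only (0.60, adjusted p = 0.00609). Genes described in tumour-associated neutrophils had 21 higher, 1 lower and 3 not past the threshold among 25 tested (camera adjusted p = 1.31e-17 and adjusted p = 0.00715 with an estimated correlation). The lectin gene Clec4n (3.58 ± 0.21), the lipopolysaccharide co-receptor gene Cd14 (4.62 ± 0.28), Il1rn (4.21 ± 0.25), Arg1 (7.67 ± 0.59) and Cd274 (2.31 ± 0.23) were higher, each with an adjusted p of at most 1.45e-06. The prostaglandin synthase gene Ptges was lower (-2.35 ± 0.33, adjusted p = 6.82e-05). The list of tumour-associated neutrophil genes moved with the epithelial markers too. TGF-beta response genes had 15 higher, 1 lower and 3 not past the threshold among 19 tested (camera adjusted p = 1.97e-16 and adjusted p = 0.00171 with an estimated correlation). Pmepa1 was at least 549-fold higher (adjusted p = 2.66e-09) and Ccn2 had 6.46 ± 0.40, adjusted p = 1.59e-08. The list moved with the epithelial markers. NF-kB targets had 21 higher, 1 lower and 4 not past the threshold among 26 tested (camera adjusted p = 9.31e-11 and adjusted p = 0.0589 with an estimated correlation). Ier3 (2.63 ± 0.17), the feedback inhibitor gene Tnfaip3 (2.44 ± 0.22) and Icam1 (2.79 ± 0.34) were higher, each with an adjusted p of at most 1.37e-05. Proteases and inhibitors had 18 higher, 1 lower and 9 not past the threshold among 28 tested (camera adjusted p = 4.90e-12 and adjusted p = 0.00891 with an estimated correlation). Serpinb2 (7.84 ± 0.34, adjusted p = 2.90e-11) and the collagenase gene Mmp13 (5.22 ± 0.31, adjusted p = 1.62e-09) were higher. Both were near absent alone (1.17 and 1.22 CPM) and with PyMT-M cells (1.40 and 2.70), as was Krt18. Survival and apoptosis regulators had 18 higher, 1 lower and 9 not past the threshold among 28 tested (camera adjusted p = 1.24e-08 and adjusted p = 0.0274 with an estimated correlation). Bcl2a1a (5.36 ± 0.38), Bcl2a1b (4.34 ± 0.35) and the death receptor gene Fas (2.42 ± 0.18) were higher, each with an adjusted p of at most 1.57e-07.

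Interferon-stimulated genes had 33 higher, 0 lower and 3 not past the threshold among 36 tested (camera adjusted p = 5.96e-14 and adjusted p = 0.0274 with an estimated correlation). Leukocyte scaling gave 28 higher and 1 lower. Cxcl10 (3.80 ± 0.23), Oasl1 (2.33 ± 0.23) and Ifit1 (1.87 ± 0.20), both encoding antiviral proteins, were higher with PyMT-N cells, each with an adjusted p of at most 3.53e-06. Chemoattractant and growth factor receptors had 23 higher, 3 lower and 7 not past the threshold among 33 tested (camera adjusted p = 3.24e-08 and adjusted p = 0.0749 with an estimated correlation). Il1r2 (3.38 ± 0.22, adjusted p = 2.07e-08) and Csf2rb (2.62 ± 0.18, adjusted p = 3.15e-08), the shared receptor chain for GM-CSF, interleukin-3 and interleukin-5, were higher. Adhesion genes had 18 higher, 4 lower and 9 not past the threshold among 31 tested (camera adjusted p = 0.00196 and adjusted p = 0.268 with an estimated correlation). The junction gene F11r (6.69 ± 0.39), Cd44 (2.15 ± 0.17), Cd47 (1.52 ± 0.18) and Itgam (1.00 ± 0.25) were higher, each with an adjusted p of at most 0.00572. Of these, F11r was near absent alone (0.97 CPM) and with PyMT-M cells (0.68), as was Krt18. The leukocyte junction gene Jaml was lower (-1.78 ± 0.20, adjusted p = 5.48e-06), and Itgb2 had 0.17 ± 0.20 (adjusted p = 0.553), with a sign that library totals and leukocyte scaling reversed (-0.048 and -0.12). Neutrophil identity genes had 13 higher, 2 lower and 4 not past the threshold among 19 tested (camera adjusted p = 0.00196 and adjusted p = 0.413 with an estimated correlation). Mxd1 (1.44 ± 0.17), a MYC antagonist, the formyl peptide receptor gene Fpr2 (1.25 ± 0.15) and Csf3r (0.61 ± 0.16) were higher and Retnlg lower (-3.18 ± 0.25), each with an adjusted p of at most 0.00874. Cxcr2 was higher (0.60 ± 0.16, adjusted p = 0.00808), though not without PyMT-N replicate 1 (0.49, adjusted p = 0.0505), and the calls of Cxcr2 and Csf3r were lost with library totals and with leukocyte scaling. S100a8 (-0.16 ± 0.18, adjusted p = 0.54) and S100a9 (-0.03 ± 0.16, adjusted p = 0.888) were not past the threshold.

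Secondary and tertiary granule genes had 6 higher, 5 lower and 5 not past the threshold among 16 tested, 6 higher and 10 lower with leukocyte scaling and 6 higher and 10 lower with library totals (camera adjusted p = 0.11 and adjusted p = 0.535 with an estimated correlation). Slpi (2.06 ± 0.17), the haptoglobin gene Hp (1.44 ± 0.16) and Mmp9 (1.58 ± 0.20) were higher, opposite to Ltf and Camp, each with an adjusted p of at most 1.64e-05. Antigen presentation genes had 11 higher, 1 lower and 12 not past the threshold among 24 tested (camera adjusted p = 0.00364 and adjusted p = 0.142 with an estimated correlation). The class I gene H2-K1, a close copy of other class I genes, stood at 1.59 ± 0.15, adjusted p = 1.27e-06. Cell cycle genes had 0 higher, 18 lower and 17 not past the threshold among 35 tested (camera adjusted p = 3.87e-05 and adjusted p = 0.0539 with an estimated correlation). Cyclin A2, Ccna2 (-1.70 ± 0.23), the replication gene Mcm3 (-1.68 ± 0.26) and Top2a (-1.20 ± 0.20) were lower, each with an adjusted p of at most 1.86e-04. The list moved with the mesenchymal markers.

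Other lists also passed. Glycolysis genes had 12 higher and 2 lower of 22 (camera adjusted p = 0.0116 and adjusted p = 0.268 with an estimated correlation). Hypoxia response genes had 12 higher and 3 lower of 23 (camera adjusted p = 0.0106 and adjusted p = 0.183 with an estimated correlation). Oxidative stress genes had 11 higher and 0 lower of 22 (camera adjusted p = 0.0123 and adjusted p = 0.413 with an estimated correlation). Immediate early and heat shock genes had 15 higher and 6 lower of 31 (camera adjusted p = 0.0211 and adjusted p = 0.138 with an estimated correlation). Pattern recognition and Fc receptors had 20 higher and 4 lower of 30 (camera adjusted p = 1.43e-04 and adjusted p = 0.153 with an estimated correlation). Those left did not. Primary granule genes had 1 higher and 2 lower of 10 (camera adjusted p = 0.32). Respiratory chain genes had 0 higher and 3 lower of 47 (camera adjusted p = 0.377). Lipid storage and uptake genes had 10 higher and 4 lower of 25 (camera adjusted p = 0.281). Sterol synthesis genes had 11 higher and 2 lower of 26 (camera adjusted p = 0.11). NADPH oxidase genes had 2 higher and 1 lower of 8 (camera adjusted p = 0.328). Unfolded protein response genes had 7 higher and 3 lower of 25, and 3 higher and 3 lower with leukocyte scaling (camera adjusted p = 0.425). Monocyte and macrophage markers had 3 higher and 7 lower of 16 (camera adjusted p = 0.0764). B cell markers had 0 higher and 1 lower of 8 (camera adjusted p = 0.62). Eosinophil and basophil markers had 1 higher and 0 lower of 5 (camera adjusted p = 0.824). Dendritic cell markers had 1 higher and 0 lower of 11, and 1 higher and 1 lower with leukocyte scaling (camera adjusted p = 0.723). The median fold change, the mean and the set test did not all point the same way for B cell and for eosinophil and basophil markers. Adjusted over the list alone, 14 lists had other numbers of higher and lower genes. These were 6 and 7 for secondary and tertiary granules, 26 and 2 for chemokines and cytokines, 34 and 1 for interferon-stimulated genes and 22 and 1 for tumour-associated neutrophil genes. These were 19 and 5 for adhesion, 19 and 1 for proteases and inhibitors, 13 and 3 for the hypoxia response and 0 and 1 for respiratory chain subunits. These were 11 and 4 for lipid storage and uptake, 12 and 2 for cholesterol synthesis, 4 and 1 for the NADPH oxidase and 11 and 2 for the oxidative stress response. These were 16 and 6 for immediate early and heat shock genes and 12 and 1 for antigen presentation. At the preset correlation 19 of 30 lists were called and 8 with an estimated one. A mixed split also gave 19 list calls.

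**Figure D4:**
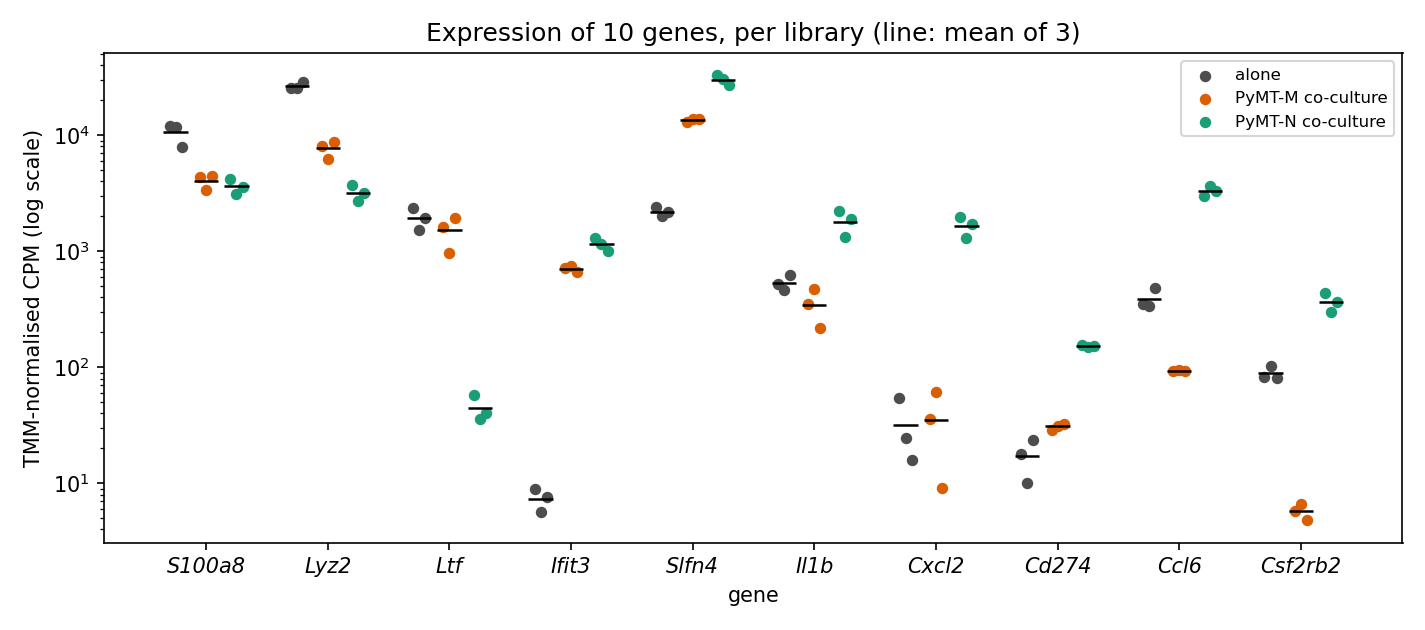
TMM-normalised CPM of 10 genes on a log scale; points are single libraries and lines are means of 3. Slfn4 and Ifit3 are higher in both co-cultures than alone, whereas Ccl6 and Csf2rb2 are higher than alone with PyMT-N cells and lower with PyMT-M cells.

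Genes called in the same direction in both co-cultures were counted to ask how much the responses overlapped. There were 2275 shared higher genes, such as Ifit3, Rsad2, Slfn4, Myc, Tead1 and Aebp1, and 2247 shared lower ones, such as Prss34, Lyz2, Mpo, Gstm1 and Cat. Independent lists of these sizes would share 995 and 790.2. These counts hold for trimmed-mean scaling. With leukocyte scaling only 184 genes were lower with PyMT-M cells than alone, so at most 184 could be shared lower. Lyz2 then stood at -0.11 with PyMT-M cells (adjusted p = 0.595). Opposite directions were called for 182 genes, 155 higher with PyMT-N and lower with PyMT-M cells and 27 the reverse. The PyMT-N over PyMT-M difference was itself past the threshold for all 182 by edgeR. Among the former were Ccl6 (3.10 ± 0.17 and -2.05 ± 0.17), Csf2rb2 (2.04 ± 0.20 and -3.93 ± 0.27), Fn1 (4.96 ± 0.60 and -4.47 ± 1.01), Thbs1 (4.36 ± 0.27 and -2.05 ± 0.29) and Clec4n (1.01 ± 0.19 and -2.57 ± 0.20). Also among them were Ptgs2 and Cd44, whose PyMT-M values of -1.05 ± 0.35 and -0.87 ± 0.17 turned to 0.62 and 0.80 with leukocyte scaling and were not past the threshold with library totals (-0.54 and -0.35). That scaling also ended the PyMT-M calls of Ccl6 (-0.38, adjusted p = 0.15), Fn1 (-2.82, adjusted p = 0.0613) and Thbs1 (-0.38, adjusted p = 0.325), but not those of Csf2rb2 (-2.27) and Clec4n (-0.90). The PyMT-M call of Ptgs2 was lost without alone replicate 2 (-0.77) or PyMT-M replicates 1 (-0.88) or 3 (-0.82), and in a fit of the compared groups only (-0.92). The reverse held for Col1a1, Lpl (-2.95 ± 0.34 and 1.53 ± 0.30) and Zcchc24 (-1.32 ± 0.46 and 3.66 ± 0.31). The PyMT-N call of Col1a1 ended with leukocyte scaling (-1.57, adjusted p = 0.132) and that of Lpl did not (-1.60). The PyMT-N value of Zcchc24 was 0.055 with leukocyte scaling, and its call was lost without alone replicate 1 (-1.06) or PyMT-N replicates 2 (-1.22) or 3 (-1.01) and with library totals (-1.04). Across genes, which are not independent replicates, the fold changes correlated with r = 0.676 and a covariance of 3.72. In 20 simulations of unchanged groups against the same controls, edgeR shared 0 genes in each (a median of 104.5 at an unadjusted p under 0.05), and the mean correlation was 0.544 with a covariance of 0.120. The 3 control libraries cannot be halved, so part of the overlap may come from them. Both comparisons were also confounded with sorting, and both co-cultures carried tumour-type transcripts, so part may come from these too. With only the 7295 genes of at least 10 CPM alone tested 2937 were shared, against 4522 of 12012.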

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

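The tests of monocyte content and of removal by the sorter were chosen only after the results were seen, and leukocyte gene scaling after the marker counts were seen. Some genes stood out because the effects of the 2 co-cultures against alone were called in opposite directions and the difference between the co-cultures was itself called by edgeR's quasi-likelihood test. This held for 182 genes. Of those named here, 10 were higher with PyMT-N and lower with PyMT-M cells by trimmed-mean scaling, but their PyMT-M value turned positive with leukocyte scaling. The PyMT-N over PyMT-M log2 fold changes were Mxd1 (1.44), Cd44 (2.15), H2-K1 (1.59), Il1b (2.37), Csf2rb (2.62), Cd47 (1.52), Ctsc (3.11), Ptgs2 (5.86), Fas (2.42) and Ccl3 (2.22), with leukocyte-scaled PyMT-M values from 0.14 to 1.2. For these genes only the difference between the co-cultures, not an opposite response, held under both scalings. Under leukocyte scaling Ccl6 (5.15), Thbs1 (6.41) and Fn1 (9.43) had negative PyMT-M values that were no longer past the threshold (-0.38, -0.38 and -2.82, adjusted p = 0.15, 0.325 and 0.0613), so an opposite response was not upheld for them either. Clec4n (3.58), Csf2rb2 (5.97) and Cdh1 (8.52) stayed past it (-0.90, -2.27 and -2.47). Cdh1 is on the epithelial marker list, and its PyMT-N rise moved with those markers. Falls against alone, such as these with PyMT-M cells, were confounded with sorting, which leukocyte scaling does not address. Lower with PyMT-N and higher with PyMT-M cells were Lpl (-4.48), Zcchc24 (-4.98) and Col1a1 (-5.64), and the PyMT-N value of Zcchc24 was 0.055 under that scaling. The PyMT-N call of Col1a1 went from -2.95 ± 0.83 to -1.57 (adjusted p = 0.132), and only that of Lpl held (-1.60). The fall of Lpl against alone was likewise confounded with sorting.

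Epithelial markers rose as a group in PyMT-N co-culture and mesenchymal markers in PyMT-M co-culture, although these libraries were sorted. A list of adherent-cell genes outside both marker lists was fixed before its values were seen, and 13 and 13 of 15 tested were called higher in PyMT-N and PyMT-M co-culture, where tumour cell RNA needed a majority. Of the rest, 2 were lower with PyMT-N and 1 with PyMT-M cells. Tumour cells attached to neutrophils, engulfed material or free RNA may have brought these transcripts. Expression by the neutrophils themselves cannot be told apart from this in bulk libraries: 3 of the 15 genes had at most 3 counts over the alone libraries, which gives a baseline but not the cell of origin.

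Interferon-stimulated genes were higher in PyMT-N than in PyMT-M co-culture. More monocytes, macrophages or dendritic cells in the PyMT-N libraries were argued against: the log2 ratio of the monocyte and macrophage marker share was -0.0776 (SD 0.207), where the interferon list had a median of 1.5. RNA of the tumour cells stayed open. Only 2 of 6 leukocyte interferon genes set as its test, Slfn1 (0.92) and Cd300lf (1.59), were called higher with leukocyte scaling, as it predicted. Ms4a6b (-2.47) and Ms4a6c (-1.96) were called lower. The median of the 6 was -0.86. The test stays weak, because Ms4a6d, Ms4a6b and Ms4a6c fell from alone with PyMT-N cells (-2.07, -2.21 and -2.92), unlike the interferon list. With leukocyte scaling they stood at -0.71, -0.84 and -1.52, but Ms4a6b rose with PyMT-M cells (1.63). Siglec1 rose in both co-cultures (4.36 and 4.73), with no call between them (-0.38). A stronger response of the neutrophils was not tested apart from these explanations.

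Of 26 granule genes, 19 were called lower with PyMT-N and 20 with PyMT-M cells than alone. With an estimated correlation only the primary granule list with PyMT-N cells kept its call. Dilution by tumour cell RNA as the whole cause was argued against for PyMT-N co-culture, where 15 of 19 lower genes remained called lower with leukocyte scaling. For PyMT-M co-culture 6 of 20 did and 4 were called higher, between the bounds set beforehand, so dilution and a fall in granule transcripts cannot be told apart there. Removal of other or less mature marrow cells by the sorter stays open as well, because sorting and co-culture are confounded: the log2 ratio of the B cell marker share was -5.17 for PyMT-N and -2.66 for PyMT-M against alone. A response of mature neutrophils to the tumour cells was not tested apart from these.

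Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In fits of the 6 compared libraries the real splits called 5697, 5919 and 5274 genes by edgeR, and all others 0. At an unadjusted p under 0.05 the highest other splits had 434, 316 and 165 genes against 6371, 6520 and 6023. Camera called 23, 20 and 19 lists in the real splits and up to 19, 17 and 19 in others. Other splits mix both groups on each side, keep part of the real difference and add it to the spread. They cannot show what chance gives.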

How the results depend on the processing

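Leukocyte gene scaling and the limit to genes of at least 10 CPM alone were the only alternatives chosen after results were seen. Leukocyte scaling raised the genes higher than alone to 7883 with PyMT-N and 8184 with PyMT-M cells and left 615 and 184 lower. The limit, with 7295 of 12012 genes tested, left 1375 and 1192 higher than alone, 1235 higher and 917 lower between the co-cultures, and 2937 shared. With both, 524 and 145 genes were lower than alone and 680 higher with PyMT-N than PyMT-M cells. Library totals left 1913 genes lower with PyMT-M cells than alone, and an adjusted p under 0.01 left 1092 lower with PyMT-N than PyMT-M cells. All other settings kept these gene counts within 1.5 times the reported ones. An estimated correlation left 8, 4 and 8 lists called of 23, 19 and 19, and fry called 25, 27 and 25. As the mean log2 CPM of the list in place of the summed share, the epithelial difference was 5.90 from alone and 5.61 from PyMT-M for PyMT-N cells, against 5.10 and 4.5. The mesenchymal one was 4.27 for PyMT-M against alone and -2.01 between the co-cultures, against 3.60 and -1.22.

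Among the 222 gene values named in the text, called or not, leukocyte scaling kept the sign and the side of the threshold for 182. It took the call of 18, added it to 2 and reversed the sign of 20, of which Icam1 for PyMT-M against alone and Itgb2 between the co-cultures had not been called. Reversed from alone with PyMT-N cells were Tgfb1 0.35, Cd84 0.028, S100a9 0.17, Csf3r 0.60, Cxcr2 0.92, Itgam 0.74 and Zcchc24 0.055. With PyMT-M cells these were Acta2 0.72, Clec4d 0.026, Ccl3 0.40, S100a8 0.31, S100a9 0.46, Csf3r 0.26 and Cxcr2 0.60. Il1b at 1.04, Itgam at 0.025, Cd44 at 0.80, Icam1 at 0.89 and Ptgs2 at 0.62 were reversed with them too. Leukocyte scaling took the calls of Zeb1 -0.32, Cd177 -0.26, S100a8 -0.15, Itgb2 -0.31 and Col1a1 -1.57 for PyMT-N against alone and of Csf3r 0.33 and Cxcr2 0.32 between the co-cultures. For PyMT-M against alone these were Fn1 -2.82, Tle4 -2.77, Fpr1 -0.065, Mmp9 -0.15, Lyz2 -0.11, Slpi -0.053, Ccl6 -0.38, Emb -0.037, Ftl1 -0.34, Itgb2 -0.19 and Thbs1 -0.38. Between the co-cultures Itgb2 went to -0.12, and to -0.048 with library totals. These also took the calls of Cxcr2 -0.17, Itgam -0.37 and Zcchc24 -1.04 for PyMT-N against alone, Acta2 -0.43, Il1b -0.099, Cd44 -0.35 and Ptgs2 -0.54 for PyMT-M and Csf3r 0.39 and Cxcr2 0.38 between the co-cultures. Limma-voom gave Arg1 -1.12 and Vegfa -0.066 for PyMT-M against alone, neither called by trimmed-mean scaling. Other size factors, filters, DESeq2, edgeR settings and the fit of the compared groups reversed none, and each took at most 4 calls and added at most 1. The calls taken were those of Il1b and Ptgs2 for PyMT-M and of Itgam and Vegfa for PyMT-N against alone.

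Leaving out each library in turn gave 3141 to 3907 higher and 2424 to 3275 lower genes for PyMT-N against alone, 2964 to 3648 and 2893 to 3857 for PyMT-M, and 1920 to 3009 and 1315 to 2621 between the co-cultures. Shared genes ran from 3790 to 5190, and lists called from 22 to 23, 19 to 20 and 19 to 21. Signs changed in uncalled genes: for PyMT-M against alone Arg1 ran from -2.59 (without PyMT-M replicate 3) to 4.74 (without alone replicate 2), Cxcl2 from -0.51 (without PyMT-M replicate 2) to 0.78 (without alone replicate 1) and Vegfa from -0.14 (without alone replicate 3) to 0.55 (without alone replicate 2). Between the co-cultures S100a9 ran from -0.16 (without PyMT-M replicate 3) to 0.14 (without PyMT-M replicate 1) and Itgb2 from -0.011 (without PyMT-N replicate 1) to 0.33 (without PyMT-N replicate 2).

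Libraries of all groups carry the same replicate numbers, but these did not pair them: correlations of the deviations of same-numbered libraries ran from -0.0781 to 0.0285, with 0 of 9 over 0.1. With the replicate block edgeR called 3411 higher and 2692 lower genes for PyMT-N against alone, 3274 and 3243 for PyMT-M, 2228 and 1739 between the co-cultures and 4305 shared, and camera 22, 18 and 21 lists. Among named genes the block changed only the Il1b call for PyMT-M against alone (-0.63, adjusted p = 0.0565).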

Other observations

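The gene families below, and the GM-CSF hypothesis though not its gene list, were chosen only after the results were seen. Csf2rb2, Csf2rb and Ccl6 were higher in PyMT-N than in PyMT-M co-culture, and a candidate explanation is a stronger GM-CSF or STAT5 response. A list of 5 response genes was fixed before its values were seen, and 3 of 3 tested were called higher in PyMT-N co-culture by edgeR. These were Cish (5.99 ± 0.38, adjusted p = 4.15e-09), Socs3 (2.51 ± 0.34, adjusted p = 4.95e-05) and Socs2, with 557 counts against 0 (adjusted p = 2.14e-08). Leukocyte scaling left Cish at 5.75 and Socs3 at 2.16. Other cytokines that act through STAT proteins could give the same result, and tumour cell RNA was not excluded as a source.

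Cytosolic aminoacyl-tRNA synthetase genes rose in both co-cultures, 16 of 20 with PyMT-N (camera adjusted p = 4.31e-04 and 0.0434 with an estimated correlation) and 18 with PyMT-M cells (3.40e-07 and 0.00883). Chaperonin genes did so for 7 and 8 of 8 (9.76e-04 and 0.0515 with PyMT-N, 1.09e-07 and 0.00883 with PyMT-M cells). None of these genes was lower in either co-culture by edgeR under any of the 3 scalings. Ribosomal protein genes were higher for 17 and lower for 10 of 78 with PyMT-N and higher for 43 and lower for 1 with PyMT-M cells, and with leukocyte scaling 71 and 78 were higher. Vacuolar ATPase genes fell in 8 and 11 of 15 by trimmed-mean scaling, but 10 and 8 were higher with leukocyte scaling. Growing cells express synthetase, chaperonin and ribosomal genes strongly, so their source was not resolved.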
